A study of Homo sapiens with 16 samples.

How the data were processed

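Guide RNA sequences amplified from genomic DNA were counted in a genome-wide CRISPR/Cas9 loss-of-function screen with the Brunello guide library in K562 cells, a human chronic myeloid leukaemia line, that carried a miR-7 reporter. The cells were wild type (WT) or lacked CYRANO, a long noncoding RNA that triggers the decay of the microRNA miR-7. Each genotype was read in sorted and in unsorted cells, and the column names call the sorted cells dim; the gate itself is not given in the sources used here. The labels describe 16 samples, which are 8 libraries each sequenced in 2 runs, and the table holds 1 column per library. How the 2 runs were combined is not given in the sources used here. The column names give genotype, sort and a number, so each column was placed in its group, and the unnumbered column of a group was called library 1. That left 4 groups of 2 libraries: WT unsorted, WT sorted, CYRANO knockout unsorted and CYRANO knockout sorted. The labels do not state that the 2 libraries of a group came from separate cultures. The guide p-values of the main test measure the spread between these libraries alone. Gene p-values compare a gene's guides with random guides, and list and overlap p-values take genes as units. None of these measures the spread between libraries directly. Sorted cells and unsorted cells also had their DNA extracted by different methods per the labels, so extraction and sorting cannot be told apart.

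The deposited values are RPM of each guide, its reads scaled to a common library total of 1 M (mega) reads, plus an offset of 1. This was settled from the values: the lowest value is 1, and the value minus 1 is a whole multiple of the step of 1 read in 100.0% of values within a tolerance of 0.05 of a step. The submitters' processing notes name MAGeCK, without a version or a role. The step sizes put the libraries at 33.7 to 67.9 M reads. The 65535 guides of the table hold 27.9 to 56.5 M of these, between 82.7% and 83.5% of each library. The remaining reads belong to guides that were not analysed here: the table ends with 3 guides of GDPD4, where most genes have 4. It carries 16383 gene labels, of which 15487 equal a current RefSeq symbol; older symbols are printed as the table gives them, with TCEB1 for Elongin C and TCEB2 for Elongin B. A further 23 labels, with 100 guides, had been turned into dates and were not tested as genes. Of the table's guides, 0 are labelled as non-targeting controls. A count of 0 reads allows up to 0.0442 to 0.0891 RPM per library (3 counts), a floor that covers counting error only, since PCR reads without molecular identifiers are not independent molecules.

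Guides with a mean below 1.034 RPM over the 8 libraries, 0.1 of the median guide mean, were left out (1032 guides), which left 64503 guides and 16346 genes with at least 2 guides; 37 labels were not tested. The test ran on log2 of the deposited value plus a pseudocount of 1. limma 3.58.1 in R 4.3.3 fitted the 4 group means over all 8 libraries (4 residual degrees of freedom) with a trended variance. There were 4 comparisons: WT sorted minus unsorted, CYRANO knockout sorted minus unsorted, the WT sort effect minus the knockout sort effect (the genotype difference), and unsorted knockout minus unsorted WT. Guides were ranked by one-sided p in each direction and combined per gene by robust rank aggregation (RRA) over guides with p up to 0.25. Gene p-values came from 10000000 random guide sets of the same size, so the smallest possible p is 1.0e-07, and were adjusted by the Benjamini-Hochberg method over the 16346 genes in each direction and comparison, with a threshold of 0.05. The number of random sets was raised after first results had been seen, because adjusted p-values close to the threshold moved with the draw; the depletion of ADAM23 in the WT sort was past the threshold in an earlier draw and is not in the draw reported. A gene's log2 fold is the mean over its kept guides, with a standard error (SE) from the spread between the 2 libraries per group. Summed RPM per gene are given as mean and SD. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

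The 21 gene lists were: the 6 genes of the ligase the study is named for (ZSWIM8, CUL3, TCEB1, TCEB2, ARIH1 and RBX1), neddylation, the COP9 signalosome, other cullin-RING components, other ZSWIM genes, microRNA biogenesis, the RNA-induced silencing complex (RISC), the Argonaute phosphorylation cycle, Argonaute loading chaperones, deadenylation and decapping, microRNA tailing and trimming, nonsense-mediated decay, N6-methyladenosine (m6A) writers, readers and erasers, HUSH and its partners, Mediator, SAGA, erythroid factors of K562 cells, BCR-ABL signalling, the proteasome, ribosomal proteins, and olfactory receptors, which are rarely expressed outside the olfactory epithelium. A list was tested by the median log2 fold of its genes against 10000 random lists of the same size, matched on decile of mean guide level, two-sided, with Benjamini-Hochberg adjustment over all lists and comparisons. The excess is the list's median minus the median of its matched random lists. The ligase list is the study's own, so its result is not independent evidence. A further 11 lists (DSIF and NELF, the PAF1 complex, the THO complex, Integrator, EIF3, RNA polymerase I, RNA polymerase III, the small subunit processome, the cytosolic chaperonin, the MCM helicase and the mitochondrial ribosome) were added after the values were seen and stand in the closing section. Per comparison the text names the 12 genes highest in the enriched and the 6 highest in the depleted direction by gene p, ties by fold, whether or not past the threshold, the 6 ligase genes, and the 2 members of each list with the smallest p, of which not all are reported here; any other gene named was chosen after its values were seen. Groups, comparisons, tests, the 21 lists, the rule for named genes and the alternatives, except those named as added, were fixed before the data were examined.

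The procedure was tested on simulated data made from the measured unsorted guide levels and library totals. The sorted libraries were drawn through a limited number of sampled genomes. Every guide of a changed gene was given the same fold, and no outlying guide was simulated. The rates may therefore be better than those of the measured screen. Of 50 genes simulated at each fold, the WT sort test called 6 at 2-fold, 32 at 4-fold, 50 at 8-fold and 50 at 16-fold, with 0 unchanged genes called enriched and 1 called depleted. The genotype difference called 4, 14, 47 and 49 of 50, with 2 unchanged genes called. Of 200 lists of 20 unchanged genes, 13 had a p under 0.05 (6.5%). The alternatives changed 1 choice at a time: the scaling (median of all kept guides, or of olfactory receptor guides, made equal), the pseudocount (5, 0.5 or none beyond the offset), the filter (none, or a stricter one), the libraries in the fit, a replicate block, the guide test (a negative-binomial test in the manner of MAGeCK, or limma-voom on reads calculated back from the steps), the gene test (RRA over all guides, guides ranked within 20 bins of level, or the mean moderated t against olfactory receptor guides), the level on which random lists were matched, and each library left out in turn.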

Results

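The screen asked which gene losses place K562 cells with a miR-7 reporter in the sorted, dim population, and which of these effects need CYRANO, the noncoding RNA that directs the decay of miR-7. MicroRNA decay of this kind needs a cullin-RING ubiquitin ligase built from ZSWIM8, CUL3, Elongin B, Elongin C, ARIH1 and RBX1. Guides were counted in 8 libraries, 2 each from WT unsorted, WT sorted, CYRANO knockout unsorted and CYRANO knockout sorted cells. Guide counts from DNA measure no expression, so the loss of CYRANO itself is not checked by these data. The 4 unsorted libraries held 33.7 to 43.1 M reads (M, mega), with a median of 347 to 446 reads per guide. The 4 sorted libraries held 47.9 to 67.9 M reads, with a median of 399 to 580. Guides with 0 reads made up 0.09% to 0.133% of the table in the unsorted libraries, and 11.6%, 22.6%, 17.3% and 16.5% in WT sorted libraries 1 and 2 and knockout sorted libraries 1 and 2.

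Replicate libraries were close before the sort and far apart after it. Across guides, log2 values of the 2 libraries of a group correlated at r = 0.967 in unsorted WT and r = 0.960 in unsorted knockout cells. In the sorted groups they correlated at r = 0.344 and r = 0.315. Guides are not independent replicates. In the sorted libraries 26.3% to 28.4% of guides had less than 1 RPM, against 1.21% to 1.41% in the unsorted libraries. A ZSWIM8 guide was the most abundant of all guides in both WT sorted libraries, at 1437 and 874 RPM, beside a QKI guide at 1133 and 642 RPM. The same QKI guide was the most abundant in knockout sorted library 2, at 766 RPM. In knockout sorted library 1 it was a lone guide of NEMF, a factor of ribosome-associated quality control, at 4288 RPM, while the other 3 NEMF guides stood at 3.44 to 8.23 RPM. The median gene had a log2 fold of −0.47 in the WT sort and −0.49 in the knockout sort. Gene folds are printed as measured, and gene lists are given relative to random lists matched on guide level. Guide calls moved with the shift. limma called 73 guides enriched and 1583 depleted in the WT sort and 77 and 1604 in the knockout sort. Once the medians of all guides were made equal it called 5 and 3, all enriched.

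**Figure D1:**
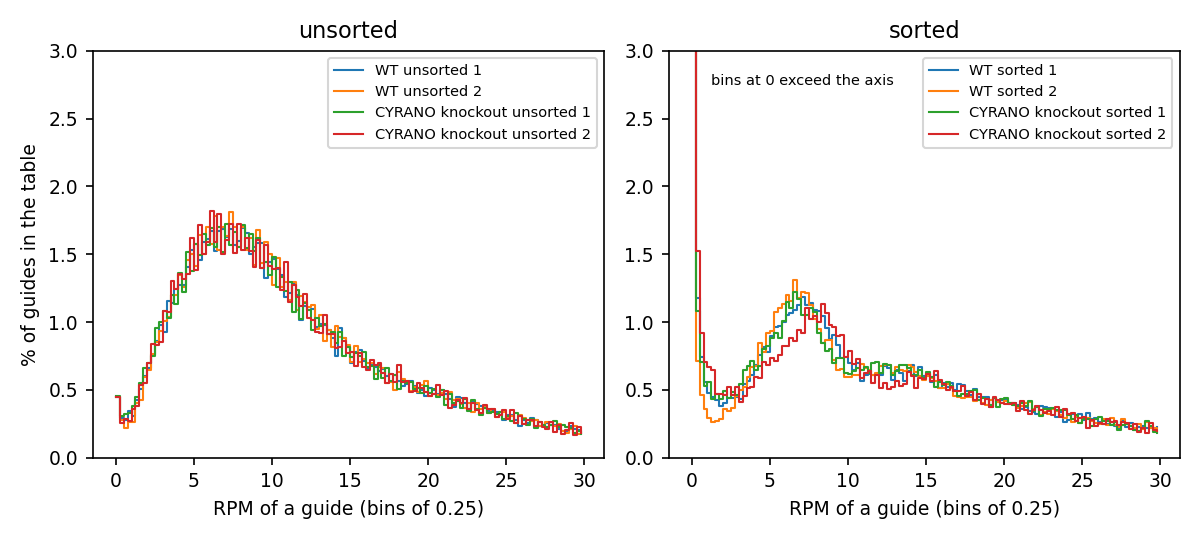
Share of guides (percent) in bins of RPM for the unsorted and the sorted libraries; bins at 0 run beyond the axis. Between 26.3% and 28.4% of guides lie below 1 RPM in the sorted libraries, against 1.21% to 1.41% in the unsorted ones.

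The first comparison, WT sorted against WT unsorted cells, asked which losses enrich cells in the dim population when CYRANO is present. Guides against ZSWIM8, the substrate receptor of the ligase, went from 44.9 ± 3.32 RPM summed over 4 guides in unsorted cells to 1713 ± 718 RPM in sorted cells (SD, n = 2 libraries each), a log2 fold of 4.63 ± 0.54 (SE; adjusted p = 0.000234). Elongin B (TCEB2), which with Elongin C links substrate receptors to a cullin, was enriched by 4.45 ± 0.29 and Elongin C (TCEB1) by 3.14 ± 0.52, both at the same adjusted p. RBX1, the RING subunit that recruits ubiquitin-charged enzymes to cullins, was enriched by 1.99 ± 0.43 (adjusted p = 0.000865, 3 guides). ARIH1, a ligase that starts ubiquitin chains on cullin substrates, was enriched by 1.85 ± 0.53 (adjusted p = 0.00339). CUL3, the scaffold, stood at 1.91 ± 1.19 and did not pass over all genes (adjusted p = 0.0727). Its guides summed to 464 RPM in WT sorted library 1 and 78.2 RPM in library 2 against 31.1 and 31.5 RPM unsorted. Of the 6 ligase genes 5 were called over all genes and 6 when adjusted over the list alone. The list's median exceeded that of matched lists by 2.86 (adjusted p = 0.0024). This list is the study's own and not independent evidence. Without WT sorted library 1 the call of ARIH1 ended (1.32, adjusted p = 0.325). CUL3 passed without WT sorted library 2 (3.10, adjusted p = 0.0308) or WT unsorted library 2 (1.91, adjusted p = 0.0225), and in 4 of 14 alternatives other than leaving out 1 library (adjusted p of 0.00201 to 0.621 over the 14). With limma-voom all 5 calls ended (adjusted p of 0.154 for ZSWIM8, 0.0514 for TCEB2, 0.0655 for TCEB1, 0.0928 for RBX1 and 0.406 for ARIH1). Those of ARIH1 and RBX1 also ended with the libraries of the 2 groups alone, and that of ARIH1 with the stricter filter. Over the 14 alternatives other than leaving out 1 library the fold of ZSWIM8 stayed between 4.13 and 5.08 and that of ARIH1 between 1.46 and 2.37. With a library left out, the lone library of its group is assumed to vary like the others.

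Beyond the ligase, the highest genes of the WT sort were QKI, an RNA-binding protein of the STAR family, at 3.69 ± 0.19, PCBP1, a poly(C)-binding protein, at 3.15 ± 0.73, ILF2, a nuclear factor of RNA metabolism, at 3.15 ± 0.12, and NXT1, a cofactor of mRNA export, at 2.98 ± 0.44 (adjusted p = 0.000234 for each, 4 of 4 guides higher). The next were CDK12, a kinase of the RNA polymerase II tail, at 3.04 ± 1.04, SPTY2D1, a histone chaperone, at 2.49 ± 0.11, and the elongation factor ELOF1 at 2.33 ± 0.38 (adjusted p = 0.000272 for each). At the same adjusted p stood the translation initiation factor subunit EIF3M at 1.86 ± 0.09, and the nuclear pore protein TPR at 1.70 ± 0.16. In total limma with RRA called 58 genes enriched and 0 depleted among 16346, against 865 and 980 at an unadjusted p under 0.05. A share of about 0.05 of genes is expected there by chance in each direction and comparison, so such counts do not measure further hits. The negative-binomial test called 81 and 0, limma-voom 19 and 0. The former took its spread from the unsorted libraries alone, and gave 53606 of 64503 guides an unadjusted p under 0.05. Every one of the 58 had more summed RPM in each WT sorted library than in either WT unsorted library. Their choice from these same libraries favours this. On the log scale AFF4 stood at −0.36 without WT sorted library 2 and STRAP at 0.09 without WT sorted library 1. Depleted genes were led by ADAM23, a cell-surface member of the ADAM family, at −1.57 ± 0.30 (adjusted p = 0.0572). It was followed by ZSWIM3 at −1.85, the purine synthesis enzyme GMPS at −1.35, γ-tubulin TUBG1 at −1.32 and the transcription factor PLAG1 at −1.13 (adjusted p = 0.535 for each). Without WT sorted library 1, 14 of the 58 calls remained among 18. ELOF1 (1.96, adjusted p = 0.183) and SPTY2D1 (2.60, 0.0783) lost theirs while CDK12 kept it at 2.01. Without WT sorted library 2, 27 remained among 43, and SPTY2D1 (2.38, 0.196) again lost its call.

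**Figure D2:**
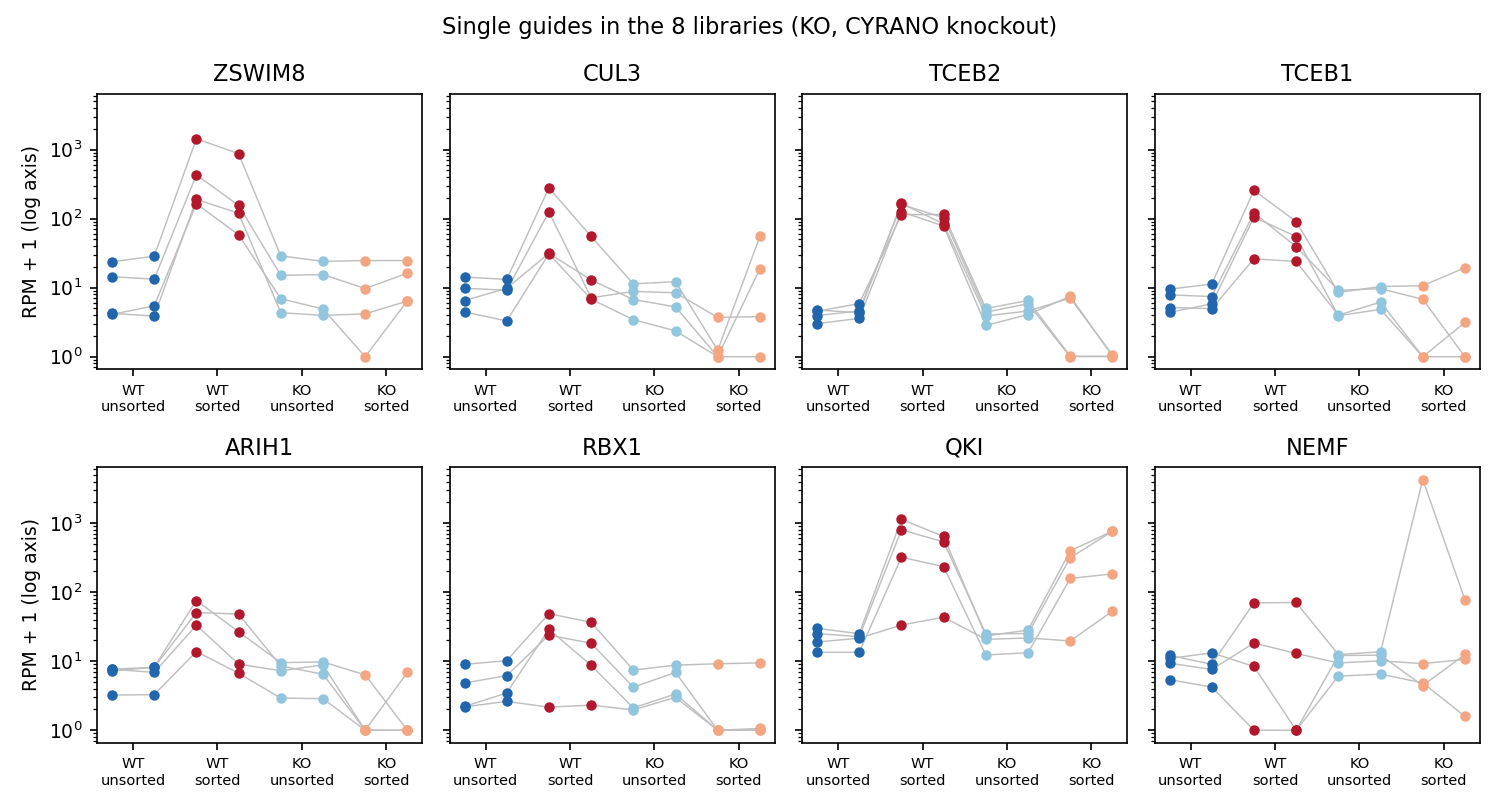
RPM plus 1 on a log axis for single guides of the 6 ligase genes, QKI and NEMF in each of the 8 libraries; grey lines join the same guide. Summed over guides, ZSWIM8 stands at 2221 and 1205 RPM in the WT sorted libraries and at 35.6 and 49.8 RPM in the knockout sorted ones, while QKI stands high in all 4 sorted libraries.

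Among the lists of ubiquitin genes, neddylation, the attachment of NEDD8 that activates cullins, had 1 of 13 members called over all genes and 6 adjusted over the list alone in the WT sort. Its median excess of 0.33 did not pass (adjusted p = 0.139). NAE1, a subunit of the NEDD8-activating enzyme, was enriched by 2.07 ± 0.11 (adjusted p = 0.00156). The NEDD8-conjugating enzyme UBE2M stood at 2.13 ± 0.49 (adjusted p = 0.157). The COP9 signalosome, which removes NEDD8 from cullins, exceeded matched lists by 0.64 (adjusted p = 0.0129). It had 0 of 9 members called over all genes by limma and GPS1 (0.67 ± 0.33) and COPS2 (0.98 ± 0.08) adjusted over the list alone. Other cullin-RING components (excess 0.07, adjusted p = 0.765) and other ZSWIM genes (−0.14, adjusted p = 0.697) did not differ from matched lists. UBE2D1 stood at −1.30 and CUL2 at −0.72. The proteasome list also did not differ (0.09, adjusted p = 0.636), although its member SHFM1 was enriched by 1.63 ± 0.32 (adjusted p = 0.0427). The COP9 excess fell below the threshold without WT unsorted library 1 (0.37, adjusted p = 0.188) or WT sorted library 2 (0.39, adjusted p = 0.370), and was 1.32 without WT sorted library 1. The call of NAE1 ended without WT sorted library 1 (1.96, adjusted p = 0.319) or 2 (2.18, adjusted p = 0.293). That of SHFM1 ended without WT sorted library 1 (1.31, adjusted p = 0.601).

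Among the lists of RNA control, m6A genes exceeded matched lists by 0.43 (adjusted p = 0.0291), with 3 of 14 members called and 5 adjusted over the list alone. The genes called were ZC3H13 at 2.0 ± 0.16 (adjusted p = 0.00156), METTL3 at 1.49 ± 0.45 (0.0118) and METTL14 at 1.0 ± 0.34 (0.0278), which belong to the complex that writes the mark. Deadenylation and decapping exceeded matched lists by 0.42 (adjusted p = 0.0129). CNOT3, a subunit of the main deadenylase complex, was enriched by 1.42 ± 0.11 (adjusted p = 0.0204), and CNOT3 and DDX6 were called adjusted over the list alone. Ribosomal proteins exceeded matched lists by 0.40 (adjusted p = 0.0024), with 0 of 83 members called by limma over all genes or over the list alone. RPS25 stood at 1.18 ± 0.48 (adjusted p = 0.157) and RPS27A at −1.71 ± 0.02. The list's own median was −0.24, with 22 of 83 members above 0, so the excess is relative to matched lists that stood lower. The m6A excess missed the threshold without WT unsorted library 1 (0.37, adjusted p = 0.0706), WT sorted library 1 (0.44, adjusted p = 0.105) or WT sorted library 2 (0.41, adjusted p = 0.2). That of deadenylation and decapping did so without WT sorted library 1 (0.36, adjusted p = 0.132) or WT sorted library 2 (−0.04, adjusted p = 0.911). Each of the 4 called genes lost its call without either WT sorted library (adjusted p of 0.0791 to 0.842).

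Genes that make and load microRNAs did not rise. The microRNA biogenesis list stood at −0.40 against matched lists in the WT sort (adjusted p = 0.0707), or −0.039 without WT sorted library 1. XPO5, which exports precursors, stood at −1.53 ± 0.38 and SRRT at −1.01 ± 0.13, both past no threshold. RISC (0.17, adjusted p = 0.643) and the loading chaperones (−0.16, adjusted p = 0.609) did not differ, with AGO2 at −1.5 ± 0.57. The Argonaute phosphorylation cycle had 2 measured members, CSNK1A1 at 1.40 ± 0.37 and PPP6C at 0.99 ± 0.50. limma called 0 of them over all genes and both adjusted over the list alone. The excess of 1.57 had an adjusted p of 0.0513, or 0.0485 without WT unsorted library 1 (1.58). Enzymes of microRNA tailing and trimming did not differ as a list (0.17, adjusted p = 0.406), though TUT1, a terminal uridylyltransferase, was enriched by 1.11 ± 0.49 (adjusted p = 0.0472). Nonsense-mediated decay (0.03, adjusted p = 0.965), SAGA (−0.11, adjusted p = 0.636), HUSH (0.00, adjusted p = 1), BCR-ABL signalling (−0.05, adjusted p = 0.934), erythroid factors (−0.16, adjusted p = 0.590) and olfactory receptors (−0.06, adjusted p = 0.333) did not differ from matched lists. Mediator did not either (−0.03, adjusted p = 0.917), while its kinase module cyclin CCNC was enriched by 0.83 ± 0.04 (adjusted p = 0.00847). The call of CCNC ended without WT sorted library 1 (0.80, adjusted p = 0.588) or 2 (0.87, adjusted p = 0.366). That of TUT1 ended without WT unsorted library 1 (1.05, adjusted p = 0.0887), WT sorted library 1 (0.62, adjusted p = 0.887) or WT sorted library 2 (1.60, adjusted p = 0.196), and TUT1 was called in 6 of 14 alternatives other than leaving out 1 library.

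**Figure D3:**
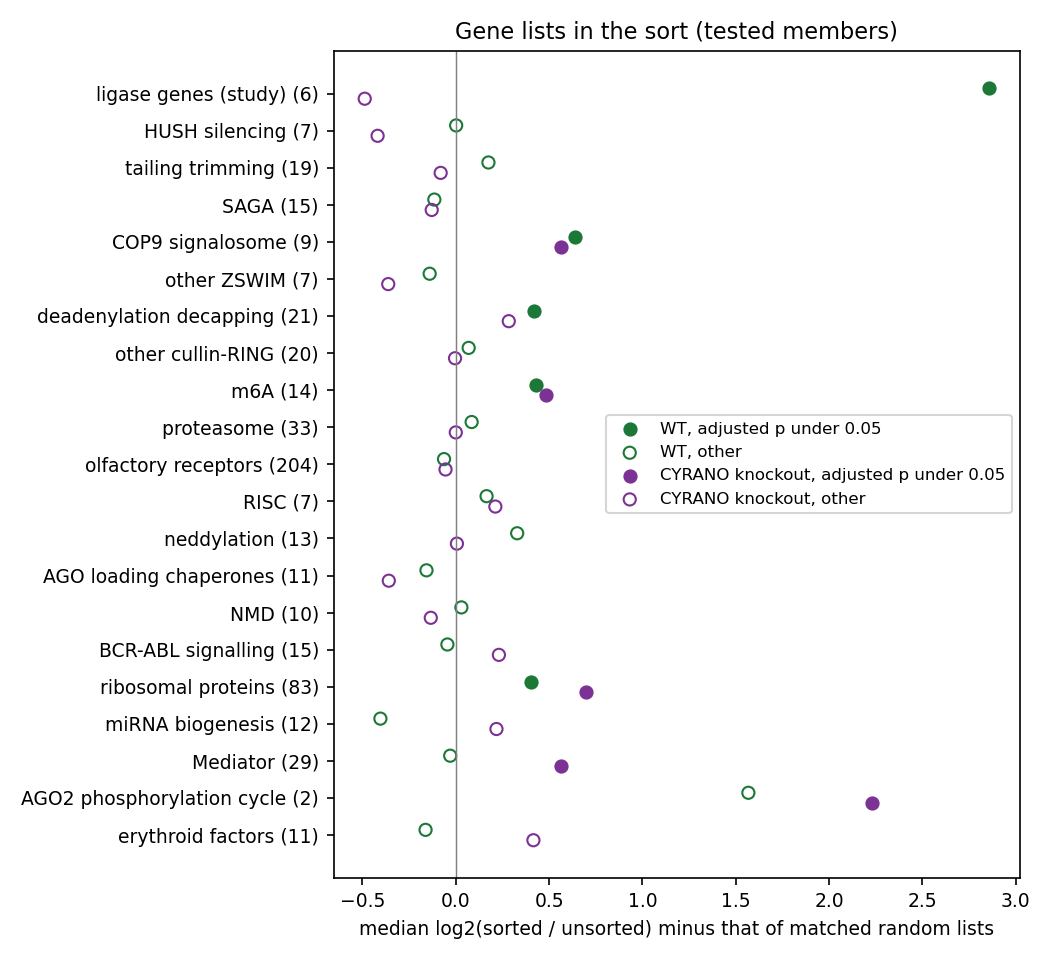
Median log2 fold (sorted over unsorted) of each of the 21 gene lists minus that of matched random lists, for WT (green) and CYRANO knockout (purple); filled points have an adjusted p under 0.05. The ligase list stands at 2.86 in WT and at −0.49 in the knockout.

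In CYRANO knockout cells the same sort asked which losses act without the decay trigger. None of the 6 ligase genes was called by limma with RRA, over all genes or over the list alone. ZSWIM8 stood at −0.23 ± 0.40, with 42.7 ± 10.1 RPM in sorted and 47.9 ± 4.78 RPM in unsorted cells (SD, n = 2). CUL3 stood at −0.57 ± 1.0, TCEB1 at −0.83 ± 0.14, TCEB2 at −0.95 ± 0.53, RBX1 at −0.79 ± 0.22 and ARIH1 at −1.43 ± 0.02. The guides of CUL3 summed to 2.95 RPM in knockout sorted library 1 and 75.2 RPM in library 2, against 26.4 and 24.3 RPM unsorted. Its fold was 0.43 without library 1 and −1.58 without library 2, and it was called in neither case. The list had an excess of −0.49 (adjusted p = 0.101, and −0.67 with adjusted p = 0.0189 without knockout unsorted library 1). The highest gene was PPP6C, the catalytic subunit of the phosphatase that acts on Argonaute, at 3.58 ± 0.63, where RPM went from 21.5 ± 2.20 to 386 ± 218. QKI followed at 3.21 ± 0.48, the elongation factor SUPT5H at 2.93 ± 0.41, NXT1 at 2.84 ± 0.17, PCBP1 at 2.76 ± 0.35, PRDM4 at 2.69 ± 0.28, SPTY2D1 at 2.44 ± 0.89 and TPR at 1.96 ± 0.08 (adjusted p = 0.000204 for each, 4 of 4 guides higher). The helicase DHX33 (1.84 ± 0.13, adjusted p = 0.000908), BANP (1.83 ± 0.27, 0.00294), ILF2 (1.5 ± 0.52, 0.00297) and POLR1A, the largest subunit of RNA polymerase I (2.04 ± 0.27, 0.00572), completed the 12 highest. Without knockout sorted library 1 the calls of PCBP1 (2.43, adjusted p = 0.0753), PRDM4 (2.96, 0.0517), BANP (1.61, 0.296) and POLR1A (2.27, 0.385) ended. Without knockout sorted library 2 those of SUPT5H (2.54, 0.0785), PRDM4 (2.42, 0.167), BANP (2.06, 0.273), ILF2 (0.99, 0.218) and POLR1A (1.80, 0.302) ended, and SPTY2D1 kept its call at 1.55.

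The knockout sort called 47 genes enriched and 0 depleted by limma with RRA, against 905 and 898 at an unadjusted p under 0.05. The negative-binomial test called 106 and 0, limma-voom 13 and 0. Each of the 47 had more summed RPM in either sorted library than in both unsorted libraries, which their choice favours too. ADAM23 again led the depleted genes at −1.26 ± 0.41 (adjusted p = 0.103), followed by POLA1 at −1.59, KCNN1 at −1.95 and SYT3 at −1.17 (adjusted p = 0.348 for each), COG4 at −1.78 (0.475) and DCST2 at −2.12 (0.560). Without knockout sorted library 1, 10 of the 47 calls remained among 22, and without knockout sorted library 2, 9 remained among 13.

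Ribosomal proteins exceeded matched lists by 0.70 in the knockout sort (adjusted p = 0.0024), again with 0 of 83 members called by limma over all genes or over the list alone. Mediator, the coactivator of RNA polymerase II, exceeded them by 0.56 (adjusted p = 0.0024). limma called 0 of 29 members over all genes and MED8, MED12 and CCNC adjusted over the list alone, and MED8 stood at 1.39 ± 0.57. m6A genes exceeded them by 0.48 (adjusted p = 0.0093), with METTL3 called at 1.39 ± 0.66 (adjusted p = 0.0308) and 4 members called over the list alone. The COP9 signalosome exceeded them by 0.56 (adjusted p = 0.0399) with 0 members called by limma on either scale. Its list test passed in 4 of 5 alternatives other than leaving out 1 library (adjusted p up to 0.0831). The 2 members of the Argonaute phosphorylation cycle stood 2.23 above matched lists (adjusted p = 0.0024) through PPP6C, with CSNK1A1 at 0.12 ± 0.40. CAND1, which exchanges cullin receptors, was enriched by 0.96 ± 0.07 (adjusted p = 0.0196) in a neddylation list that did not differ (0.01, adjusted p = 1). Without knockout sorted library 2 the excess of Mediator was 0.13 (adjusted p = 0.654), that of m6A genes 0.08 (adjusted p = 0.861) and that of the COP9 signalosome 0.03 (adjusted p = 0.972). The last also missed the threshold without knockout unsorted library 1 (0.44, adjusted p = 0.122) and was 0.90 without knockout sorted library 1. METTL3 and CAND1 lost their calls without knockout unsorted library 1 (1.24 and 0.90, adjusted p of 0.0842 and 0.0849), knockout sorted library 1 (2.03 and 0.92, adjusted p of 0.0517 and 0.689) or knockout sorted library 2 (0.75 and 1.0, adjusted p of 0.999 and 0.393).

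The test of the genotype difference, the WT sort effect minus the knockout sort effect, asked which effects of the sort depended on CYRANO. TCEB2 differed by 5.41 ± 0.61, ZSWIM8 by 4.86 ± 0.67 and TCEB1 by 3.97 ± 0.54 (SE over 2 libraries in each of 4 groups; adjusted p = 0.000545 for each, 4 of 4 guides). These were the 3 genes called among 16346. Over the 13 alternatives other than leaving out 1 library, the sizes moved with the setting. They ran from 4.1 to 10.45 for TCEB2, 4.26 to 6.2 for ZSWIM8 and 3.01 to 8.11 for TCEB1. Guides of TCEB2 stood at 0 to 6.51 RPM in the knockout sorted libraries, where the offset and the pseudocount weigh on a log2 fold. ARIH1 stood at 3.28 ± 0.53 (adjusted p = 0.204), RBX1 at 2.77 ± 0.48 (adjusted p = 0.122) and CUL3 at 2.49 ± 1.56 (adjusted p = 0.895). ARIH1 and RBX1 were each called in 3 of 13 alternatives other than leaving out 1 library (adjusted p of 0.000613 to 0.869 and 0.000272 to 0.869), and CUL3 in 1 of 13 (0.00035 to 0.977), the negative-binomial test. For ARIH1 and RBX1 these were the negative-binomial test for both, the replicate block and the mean moderated t for ARIH1, and no filter and ranking within bins of level for RBX1. The 6 were all called adjusted over the list alone. The list exceeded matched lists by 3.59 (adjusted p = 0.0024), again as the study's own list. Further genes with a high difference were NAE1 at 2.45 ± 0.85 (adjusted p = 0.387) and, with a larger adjusted p, ZNF75A at 1.96, AAK1 at 2.58, DCLK3 at 2.14, SNN at 2.36 and POLR3B at 1.04 (adjusted p = 0.506 for each). limma called 0 genes in the other direction, against 869 at an unadjusted p under 0.05. The negative-binomial test called 34 genes up and 13 down. Its spread came from the unsorted libraries alone, and 52301 of 64503 guides had an unadjusted p under 0.05. limma-voom called 0 and 0, with adjusted p of 0.924 for ZSWIM8, 0.926 for TCEB2 and 0.968 for TCEB1. Lowest by limma with RRA were ROR1 at −1.76, C1D at −0.70, JUNB at −0.72, TNFAIP8L1 at −2.46, POLR2K at −2.07 and PMAIP1 at −1.83 (adjusted p = 0.663 for each). PPP6C stood at −2.59 ± 0.80 (adjusted p = 0.832), so its larger fold in the knockout sort was not shown to differ over all genes. It was called adjusted over its list of 2 alone, a list whose excess of −0.67 did not pass (adjusted p = 0.333). Without WT sorted library 1 limma called 0 genes (TCEB2 5.12, ZSWIM8 4.32 and TCEB1 3.45, adjusted p of 0.0719, 0.0932 and 0.255). It called 1 without WT sorted library 2 (ZSWIM8, with TCEB2 at 5.69 and TCEB1 at 4.48, adjusted p = 0.0537). It called 1 without knockout sorted library 1 (TCEB2, with ZSWIM8 at 4.47 and TCEB1 at 3.98, adjusted p of 0.307 and 0.435) and 2 without knockout sorted library 2 (not TCEB1 at 3.95, adjusted p = 0.292). RBX1 passed without knockout unsorted library 1 (2.99, adjusted p = 0.0396).

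Some lists outside the ligase also differed between the sorts. HUSH and its partners, which silence retroelements, stood 0.92 higher in the WT sort against matched lists (adjusted p = 0.0129), with MORC2 at 1.58 ± 0.22, MPHOSPH8 at −0.83 ± 0.30 and 4 of 7 members above 0. Mediator (−0.65, adjusted p = 0.0024), erythroid factors (−0.72, adjusted p = 0.0216) and ribosomal proteins (−0.28, adjusted p = 0.0063) stood higher in the knockout sort, with MED17 at −1.68 ± 0.30, KLF1, the erythroid globin regulator, at −1.5 ± 0.14, and RPL14 at −2.56 ± 0.48. In these 4 lists limma called 0 members over all genes or adjusted over the list alone. The excess of HUSH missed the threshold without each of the 4 sorted libraries (adjusted p of 0.0915 to 0.194). That of Mediator did so without WT sorted library 1 (−0.26, adjusted p = 0.336) or knockout sorted library 2 (−0.40, adjusted p = 0.126), and was −1.26 without knockout sorted library 1. Erythroid factors missed it without WT unsorted library 2, WT sorted library 2 or knockout sorted library 2 (adjusted p of 0.0765, 0.158 and 0.243). Ribosomal proteins missed it without WT unsorted library 2, WT sorted library 1, knockout unsorted library 1 or knockout sorted library 2 (−0.24, −0.25, −0.20 and −0.11, adjusted p of 0.0561, 0.102, 0.1 and 0.627). Tailing and trimming enzymes stood at 0.47 (adjusted p = 0.0513). Their excess was 0.49 without knockout unsorted library 2, 0.235 without WT sorted library 2 and 0.568 without knockout sorted library 2. The m6A genes at 0.08 (adjusted p = 0.852) and the COP9 signalosome at 0.27 (adjusted p = 0.568) did not differ between the genotypes.

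**Figure D4:**
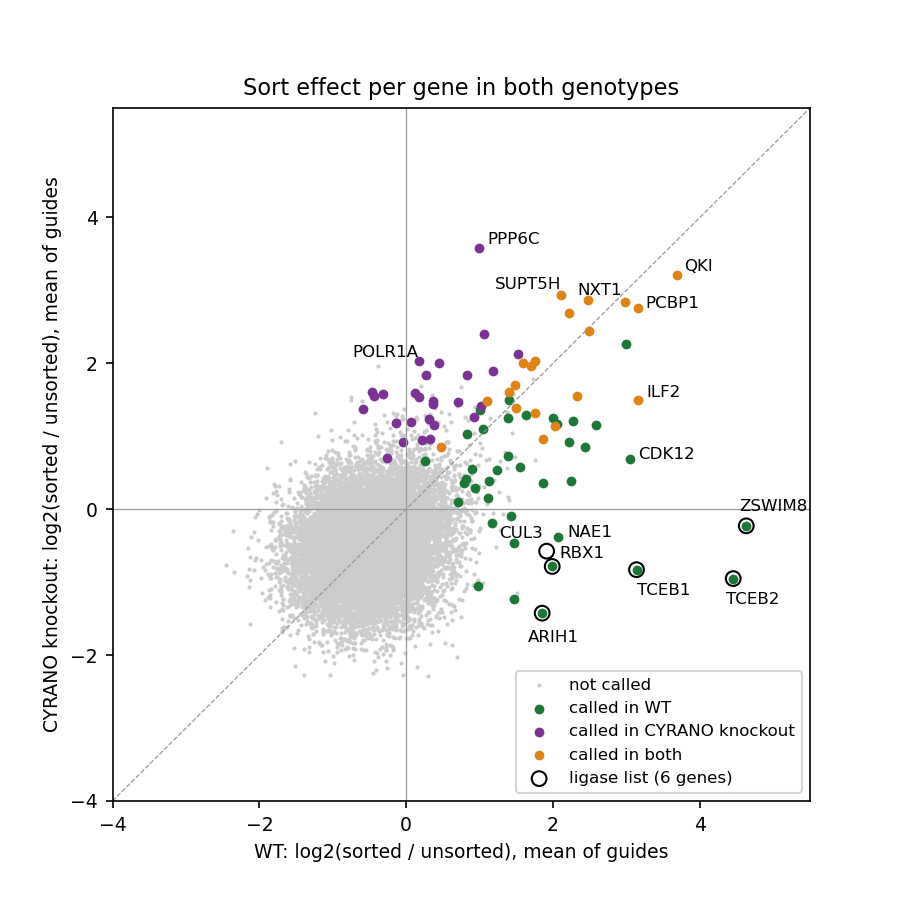
Gene log2 fold (sorted over unsorted) in WT (x axis) against CYRANO knockout cells (y axis), with called genes coloured and the 6 ligase genes circled. ZSWIM8 stands at 4.63 and −0.23, and QKI at 3.69 and 3.21.

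Many of the called genes were shared between the genotypes. Of the 58 genes called in WT and the 47 called in the knockout sort, 20 were the same, where 0.167 would be shared by chance (Fisher's exact test, one-sided, p = 2.3e-38). Both sorts were tested in 1 fit with a shared spread per guide, so their calls are not independent, as this test assumes. With the libraries of the 2 groups alone, which called 40 and 36 genes, fewer were shared. The 20 shared genes had a median log2 fold of 1.95 in WT and 1.83 in knockout cells. They included QKI, PCBP1, ILF2, NXT1, TPR, SPTY2D1, EIF3M and METTL3, together with the transcription elongation factors SUPT4H1, SUPT5H, ELOF1, NELFB and CDC73. The 38 genes called in the WT sort alone had a median of 1.47 in WT and 0.47 in knockout cells. The 27 called in the knockout sort alone had a median of 0.30 in WT and 1.49 in knockout cells. Of all these, the difference was called for the 3 ligase genes. Choosing genes by a call in 1 sort and none in the other itself sets their 2 medians apart. Those medians therefore do not show sets of genes particular to a genotype. Across all genes the folds of the 2 sorts correlated at r = 0.216, with genes that are not independent replicates. Without WT sorted library 1 or 2 the shared genes numbered 9 and 13, and without knockout sorted library 1 or 2 they numbered 8 and 6.

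The unsorted libraries asked whether the guide pool of knockout cells differed from that of WT cells before the sort, and few genes were called. The fit took its spread from all 8 libraries, including the far more variable sorted ones. In it 10 of 64503 guides had an unadjusted p under 0.05. With the libraries of these 2 groups alone 2860 guides did, below the number expected by chance, and 0 genes were called. The few calls of the main fit therefore do not by themselves show that the pools were alike. Across guides, log2 values of unsorted WT and unsorted knockout libraries correlated at r = 0.962 to 0.970. The 2 unsorted libraries of a genotype did so at r = 0.967 and 0.960. Over all guides the pools were thus about as close between genotypes as within them, which does not exclude differences of single genes. POLA1, the catalytic subunit of the primase-polymerase, was the 1 gene called, at 0.22 ± 0.02 higher in unsorted knockout cells (adjusted p = 0.0245, 3 guides), from 10.6 ± 0.43 to 12.7 ± 0.45 RPM (SD, n = 2). ZNF131 stood at 0.21 (adjusted p = 0.0556), the transcription regulator HEXIM1 at 0.13 (0.0943), PDE6B at 0.11 (0.499), PSMD4 at 0.12 (0.562) and ENPP2 at 0.13 (0.685). PTP4A1, FLVCR1, CAPN1, DCAF12L1, RPL23 and FBXO9 followed between −0.01 and 0.23 (adjusted p = 0.807 for each). limma called 0 genes in the depleted direction (653 at an unadjusted p under 0.05; 0 by the negative-binomial test and 0 by limma-voom). HIST1H2AI, TOP1MT, C19orf53, SLITRK3, DCTN6 and TERF2 ranked first in this direction, between −0.30 and −0.12 (adjusted p = 0.5 for each). The ligase genes lay between −0.26 for CUL3 and 0.11 for ZSWIM8, with a list excess of 0.02 (adjusted p = 0.665), which turned to −0.12 and passed without knockout unsorted library 2 (adjusted p = 0.0207). Erythroid factors, which include GATA1, TAL1 and KLF1, stood −0.10 against matched lists (adjusted p = 0.0118), with 0 of 11 members above 0. The call of POLA1 ended without WT unsorted library 2 (0.23) or knockout unsorted library 1 (0.20; adjusted p = 0.141 for each) and with the libraries of these 2 groups alone. It was called in 7 of 14 alternatives other than leaving out 1 library. ZNF131 passed without WT unsorted library 1 (0.34, adjusted p = 0.0417). The erythroid excess was 0.03 without WT unsorted library 2 (adjusted p = 0.724) and −0.07 without knockout unsorted library 1 (adjusted p = 0.179), against −0.25 without WT unsorted library 1 and −0.22 without knockout unsorted library 2.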

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

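Every test of an explanation in this part was chosen after the result was seen. The genotype difference, tested as the WT sort effect minus the knockout sort effect, set apart 3 genes of the ligase, with log2 differences of 5.41 for TCEB2, 4.86 for ZSWIM8 and 3.97 for TCEB1. It also set apart the list of 6 ligase genes, at 3.59 above matched lists. limma called 0 of the 3 genes without WT sorted library 1 (adjusted p of 0.0719 to 0.255). A single guide or a single sorted library as the source of the list's difference is argued against. Of the 24 guides of the 6 genes, 22 stood above their unsorted mean in both WT sorted libraries. The share was 17.2% over all guides, but the list is the study's own, so this contrast is no independent evidence. The count also covers the WT sort alone. The lowest difference of any of the 6 without any 1 library was 1.30. Weaker recovery of every enriched gene in the knockout sorts, to the degree seen for the ligase, is argued against by the other 53 genes called in WT. They kept a median share of 0.71 of their WT log2 fold above the median gene in the knockout sort (95% bootstrap interval over genes 0.62 to 0.90), against at most 0.05 for the 6. Their median fold was lower in the knockout (1.14 against 1.60), as choosing genes by their WT call alone also favours, so a smaller loss of recovery is not excluded. Guides that were already scarce in the unsorted knockout pool are argued against by a median difference before the sort of 0.02 (lowest −0.26, highest 0.11). A candidate explanation that stays open is a need for CYRANO in the effect of the ligase genes on the reporter. A gate set differently in the 2 genotypes could also contribute, which no value here tests.

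The other results set apart by the same test of the genotype difference were gene lists whose members were called 0 times by limma, over all genes or over the list alone. HUSH and its partners stood 0.92 higher in the WT than in the knockout sort against matched lists (adjusted p = 0.0129), and missed the threshold without each of the 4 sorted libraries (0.64 to 0.83). Mediator stood at −0.65 (adjusted p = 0.0024), which was −0.26 without WT sorted library 1 and −0.40 without knockout sorted library 2, both past no threshold, and −1.26 without knockout sorted library 1. The erythroid factors stood at −0.72 (adjusted p = 0.0216), and missed the threshold without WT unsorted library 2 (−0.59), WT sorted library 2 (−0.61) or knockout sorted library 2 (−0.50). Ribosomal proteins stood at −0.28 (adjusted p = 0.0063), and missed it without WT unsorted library 2 (−0.24), WT sorted library 1 (−0.25), knockout unsorted library 1 (−0.20) or knockout sorted library 2 (−0.11).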

How the results depend on the processing

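The olfactory receptor scaling and gene test, the fit with no added pseudocount, limma-voom, the ranking within bins of level and the matching of lists on unsorted level were chosen after the data were seen. Alternatives other than leaving out 1 library numbered 14, or 13 for the genotype difference. ZSWIM8, TCEB2 and TCEB1 kept their WT call and their call for the genotype difference in all but limma-voom. QKI kept its call in both sorts in all. The sizes of the genotype differences moved with the setting, for TCEB2 from 4.1 to 10.45. Each named gene, called or not, was compared under each of these alternatives. Of these comparisons 1155 kept their side of the threshold, most of them without a call, 22 gained and 28 lost a call. Direction was compared only where a call stood on either side, and 0 of those changed. Uncalled folds did change sign, as that of ZSWIM8 in the knockout sort (−1.12 to 0.04). For lists, past the threshold or not, 412 kept their side, 6 gained and 2 lost it. Counts of called guides depend most on the setting. Unless named below the cause was not tested.

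limma-voom called 19 genes in WT (16 shared with those reported), 20 guides up and 3020 down. It called 13 genes in the knockout (12 shared), 4 guides up and 2760 down, 0 genes and 495 guides up and 446 down for the difference, and 3 genes in both sorts. The mean moderated t called 112 and 113 genes, 44 in both. With the median of all guides equal, 1 gene was called depleted in WT, and 5 guides up and 0 down in WT and 3 and 0 in the knockout. Olfactory receptor guides made equal gave 1 depleted gene, 2 and 0 guides in WT, 3 and 0 in the knockout, and 2 unsorted genes. A pseudocount of 5 gave 1 depleted gene and 2 and 0 guides in WT, 1 and 0 guides in the knockout, and 0 unsorted lists. Without a filter 1 gene was depleted in WT and 3 in the knockout, and 0 unsorted genes were called. RRA over all guides gave 1 depleted gene in WT. The stricter filter gave 8 and 0 guides in WT, 3 and 0 in the knockout and 0 unsorted genes. Only the libraries of the 2 groups, with fewer degrees of freedom, gave 203 guides up and 6278 down in WT, 197 and 6297 and 1 depleted gene in the knockout, 0 unsorted genes and 10 genes in both sorts. The negative-binomial test, with its spread from the unsorted libraries alone, gave 21098 and 32071 guides in WT. It gave 106 genes and 20978 and 32299 guides in the knockout, 34 and 13 genes and 25885 and 25906 guides for the difference, and 0 genes and 101 and 20 guides unsorted. Ranking within bins of level gave 0 unsorted genes and 11 in both sorts.

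With 1 library left out, where the lone library is assumed to vary like the others, genes called enriched ranged from 18 to 65 in WT, 13 to 58 in the knockout, 0 to 4 for the difference (0 to 1 depleted), 0 to 2 unsorted (0 to 1 depleted) and 6 to 24 in both sorts. Guides ranged from 0 to 1154 up and 0 to 7373 down in WT, 0 to 1858 and 0 to 9162 in the knockout, and 0 to 2594 and 0 to 2893 for the difference. Lists past the threshold ranged from 2 to 5, 3 to 7, 1 to 6 and 2 to 5 in the order of comparisons. Of the lists past the threshold with or without the library, directions turned for deadenylation and decapping in WT (−0.041 without WT sorted library 2, up to 0.459), other ZSWIM genes in the difference (−0.93 without knockout sorted library 1, up to 0.27). Unsorted, they turned for the ligase (−0.119 without knockout library 2, adjusted p = 0.0207, up to 0.089), Mediator (0.063 without WT library 2, adjusted p = 0.0205, 0.104 without knockout library 1, 0.0021, down to −0.103), erythroid factors (0.032 without WT library 2, down to −0.248) and ribosomal proteins (0.072 without knockout library 1, adjusted p = 0.0021, down to −0.097). Lists past it in neither case changed sign too, such as m6A genes in the difference (−0.223 to 0.226).

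A replicate block, pairing libraries by number, gave 4 and 0 guides in each sort, 0 genes and 7 and 7 guides unsorted, and called ARIH1 for the difference. The values give little ground for this pairing: across guides the difference of libraries 1 and 2 correlated at 0.083 (WT) and 0.072 (knockout) between sorted and unsorted cells, and between genotypes at 0.096 unsorted and 0.014 sorted. Scaling and gene tests on non-targeting guides and fits on single runs were not run. No guide is labelled non-targeting, and the table has no column per run. edgeR was planned for deposited counts only and was not run, since the deposited values are RPM. limma-voom on reads calculated back from the steps was added instead. Small effects were called less often: of simulated changes in the WT sort 6 of 50 were called at 2-fold and 50 of 50 at 8-fold. All guides of a simulated gene shared its fold, so these rates may be better than those of the measured screen. The number of libraries was not varied.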

Other observations

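The complexes of this part, and all of its tests except the omission of single sorted libraries for the small subunit processome, were chosen after the values were seen. Several genes that control elongation by RNA polymerase II were called, and their complexes were chosen for that reason, so list medians below restate these calls in part and are no independent evidence. DSIF and NELF hold and release the paused polymerase. Of their members 4 of 6 were called in the WT and 3 of 6 in the knockout sort. SUPT4H1 stood at 2.48 ± 0.08 and 2.87 ± 0.10 and NELFB at 1.76 ± 0.71 and 1.31 ± 0.70. Without WT sorted library 1 the WT calls of SUPT5H, NELFA and NELFB ended, at folds of 2.11, 0.46 and 1.05. The median of the list was 1.57 and 1.28, or 0.76 without WT sorted library 1 and 0.71 without knockout sorted library 1, and the 2 members called in neither sort had a median of 0.03 and 0.69, against −0.47 and −0.49 for the median gene. Of the PAF1 complex, which travels with the polymerase, 3 of 6 and 1 of 6 were called, with CDC73 in both sorts. Its median was 1.30 and 0.57, the latter 0.13 without knockout sorted library 2 and 1.27 without knockout sorted library 1. Its WT calls, CDC73, CTR9 and WDR61, ended without WT sorted library 1 (1.28, 1.96 and 2.12) or 2 (1.52, 1.77 and 2.42). Of the THO complex of mRNA export, 1 of 6 was called in each sort, THOC6 at 2.03 ± 0.48 and 1.14 ± 0.22. Its median was 0.74 and 0.86, the former 0.20 without WT sorted library 1 and 1.28 without WT sorted library 2, and the 5 uncalled members had medians of 0.54 and 0.81. Of the initiation factor EIF3, 3 of 13 and 2 of 13 members were called, with EIF3D and EIF3M in both sorts. The 10 uncalled ones had medians of −0.04 and 0.61.

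Without sorted library 1 of the same genotype the calls of NELFB, CDC73, THOC6 and EIF3D ended in both sorts, and those of SUPT4H1 and EIF3M in the knockout sort (adjusted p of 0.325 to 1). Without sorted library 2 the same calls ended (0.0851 to 0.701), except that CDC73 kept its knockout call (1.84, adjusted p = 0.0449) and THOC6 its WT call (2.51, 0.00365). That of EIF3D ended also without unsorted library 1 (0.0887 and 0.0530). The genotype difference of these complexes against matched lists missed the threshold. The PAF1 complex stood at 0.68 (adjusted p = 0.0544), DSIF and NELF at −0.45 (0.188), THO at 0.25 (0.646) and EIF3 at −0.13 (0.696). With 1 library left out, the list's own median difference ran from 0.2 to 1.61 for PAF1 and −0.8 to 0.29 for DSIF and NELF. It ran from −0.3 to 0.79 for THO and −0.25 to −0.03 for EIF3. Integrator (−0.01 and −0.06, adjusted p of 0.980 and 0.876), the cytosolic chaperonin (0.13 and 0.16, 0.696 and 0.646), the MCM helicase (0.07 and 0.18, 0.880 and 0.646) and the mitochondrial ribosome (−0.06 and 0.15, 0.646 and 0.0811) did not differ from matched lists in either sort. RNA polymerase III stood 0.52 higher in the WT sort (adjusted p = 0.0366) and 0.48 higher in the knockout sort (0.0544).

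RNA polymerase I and the small subunit processome, both of ribosome assembly, were also chosen after members had been called. RNA polymerase I, which transcribes ribosomal RNA, had a median of 0.69 in the knockout and −0.05 in the WT sort. In the knockout sort 2 of 11 members were called, the subunit POLR1A and TAF1C, which is an initiation factor of this polymerase and not a subunit. Both calls ended without knockout sorted library 1 (2.27 and 1.08) or 2 (1.80 and 1.90). The small subunit processome had medians of 0.49 and −0.37, with 24 of 28 members above 0 in the knockout and 6 of 28 in the WT sort. The 25 members called in neither sort had medians of 0.38 and −0.42. UTP3 (1.53 ± 0.09), HEATR1 (1.58 ± 0.10) and EMG1 (1.37 ± 0.22) were called in the knockout sort. UTP3 (adjusted p of 0.176 and 0.439) and HEATR1 (0.564 and 0.324) were not called without knockout sorted library 1 or 2, UTP3 not without knockout unsorted library 2 (0.0697) and EMG1 not without knockout sorted library 2 (0.448). The median genotype difference was −0.94 for RNA polymerase I and −0.97 for the processome, and −0.76 for the 25 uncalled members of the latter. Without single libraries that of RNA polymerase I lay between −1.45 (without WT sorted library 1) and −0.67 (without WT sorted library 2).

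Unequal loss of these guides before the sort is argued against by a median unsorted difference of −0.05 over the 28 processome genes (lowest −0.19, highest 0.09). A single sorted library as the source of the processome's difference is argued against by a median genotype difference that stayed between −1.0 and −0.72 without each of the 4. Chance loss of scarce guides, read on a log scale, was set against summed RPM. There the ratio of sorted to unsorted was 1.98 times higher in the knockout than in WT cells (95% bootstrap interval over genes 1.60 to 2.47). The sum includes UTP3, HEATR1 and EMG1, and the list was chosen after members had been called. The interval also holds no spread between libraries, so the ratio does not settle this explanation. What stays open is whether chance loss of guides, the absence of CYRANO or a different gate may underlie the difference. Neither the absence of CYRANO nor a different gate was tested.

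Single guides of the sorted libraries gathered at a first peak of 6.62 to 8.12 RPM. The unsorted libraries had a like peak over all guides (6.88 to 7.12 RPM), but there it moved with the level of the guide, from 4.12 RPM for guides at 3 to 5 RPM to 12.38 to 12.62 RPM for guides at 11 to 15 RPM. For the same levels before the sort it lay at 6.12 to 7.38 and 6.88 to 8.38 RPM in the sorted libraries. The share of guides under 1 RPM fell with the level, from 50.8% to 53.6% at 3 to 5 RPM to 16.9% to 20.2% at 11 to 15 RPM. A candidate explanation is that few genomes were sampled per guide: the amount per genome calculated from the share of guides under 1 RPM, 6.79 to 7.37 RPM, came to 0.91 to 1.06 of the first peak, farthest from 1 at 0.91. Sequencing depth as the source is argued against, since the smallest sorted library had 1.11 times the reads of the largest unsorted one (47.9 against 43.1 M reads). The method of DNA extraction, which differed between sorted and unsorted cells, cannot be told apart from the sort.

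A single guide against NEMF, a factor of ribosome-associated quality control, reached 4288 RPM in knockout sorted library 1, the highest value of any guide in the table. The same guide stood at 69.0, 70.0 and 76.6 RPM in the other sorted libraries and at 8.01 to 12.7 RPM in the unsorted ones, while the other 3 NEMF guides stood between 0 and 17.3 RPM in the sorted libraries.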
